A study of Homo sapiens with 12 samples.

How the data were processed

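RNA was measured in HEK293T cells, a human embryonic kidney cell line, after treatment with DMSO (the solvent control), an inhibitor of the protein arginine methyltransferase PRMT1 or an inhibitor of PRMT4 (also named CARM1). Per the labels, cell lysates were spun through 10 to 50% sucrose gradients, which separate mRNAs by the number of ribosomes they carry, and each treatment gave 4 libraries: total input, mRNA with 1 ribosome, with 2 ribosomes and with 3 or more ribosomes. There were 12 libraries, 1 per group, so no replicates. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a directional NEBNext Ultra II kit, which keeps the strand of the RNA. The compounds, doses, treatment times, RNA selection and strand setting of the counting were not given in the sources used here.

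The deposited values were FPKM (fragments scaled by transcript length and library size) per Ensembl gene, rounded to 2 decimals. Per the submitters' processing notes, reads were trimmed with cutadapt 1.18, aligned with STAR 2.5.3a and quantified with RSEM, on the GRCh37 build. The columns for the ribosome fractions were named R1, R2 and R3 and were read as 1, 2 and 3 or more ribosomes, from the order of the numbers in the sample titles. No title gives a replicate number, but the column names alone do not exclude one, and every gradient value rests on this reading. The table held 15534 gene IDs, of which 15299 were matched to a symbol. The gene annotation used here was GENCODE release 29 on GRCh38. Because its build differs from that of the table, it served only for gene names, transcript lengths and for which genes have exons on opposite strands of the same place, and no coordinates are given.

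Values were analysed as log2(FPKM + 1), which understates the difference of low genes. Each difference between 2 libraries was centred on its median over 10706 named genes with a mean FPKM of at least 1 over the 12 libraries, after 259 small-RNA and clone-style symbols were left out. This centring removed a median shift of 0.68 (log2) between the PRMT1 inhibitor and DMSO inputs, 0.57 between the PRMT4 inhibitor and DMSO inputs and 0.68 between the DMSO fraction of 3 or more ribosomes and its input. All differences below are relative to those medians. Polysome association was the log2 ratio of 3 or more ribosomes to input within a treatment, and gradient position was the log2 ratio of 3 or more ribosomes to 1 ribosome.

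With 1 library per group, no test was run and no p-value is given. Genes were counted by fixed rules of size, chosen before the data were examined. The abundance rule asked for a difference of at least 2-fold in the input and of at least 1.5-fold in the same direction in each of the 3 ribosome fractions. The translation rule asked for a difference in polysome association of at least 2-fold and a difference in gradient position of at least 1.5-fold in the same direction. The profile rule asked for both ratios to be at least 2-fold within a treatment. Named genes had a mean FPKM of at least 5 and were the 8 with the highest and the 8 with the lowest difference in each inhibitor comparison (ranked by the input for abundance and by polysome association for translation) and the 5 highest and 5 lowest in the DMSO gradient. The PRMT genes were always named. Some genes that met these rules are not reported here. Of 33 gene lists fixed in advance, 31 had at least 5 measured members. For each of those, the median was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries only. Intervals beside a list median are 95% bootstrap intervals over its members (1000 draws) and do not cover the spread between cultures.

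The table gives no counts. The FPKM of genes with 1 annotated transcript fell in steps that put 1 fragment at 1.76 to 2.42 FPKM per kilobase, from which the counted fragments per library were estimated at 414 to 569, in units of 1000. At that depth the median gene had about 5.89 fragments per library, and 64.1% of genes had under 10. To show what counting alone gives, 20 sets of libraries with no treatment effect were drawn with Poisson counts at those depths. The number of genes that met the abundance or the translation rule in them is printed beside the observed number. No such number was computed for the profile rule. These simulations cover counting error only. The rules were tested on simulated data for the PRMT1 inhibitor: of 200 genes with a mean FPKM of at least 1 raised 2-, 4- or 8-fold in abundance, 23, 67.5 and 82.5% were recovered, and at a mean FPKM of at least 50 the shares were 70, 100 and 100%. For polysome association the shares were 34.5, 73 and 89% at the lower minimum, where 18.7 to 19.4% of unchanged genes also met the rule, and 28.5, 96 and 100% at the higher one, where 2.62 to 3.03% did. In the same simulation 18 of 20 lists of 30 genes raised 1.5-fold in the PRMT1 inhibitor input lay above the upper percentile limit (2000 random lists each), and 11 of 200 unchanged lists lay outside the limits.

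The overlap of the 2 inhibitors was set beside the overlap of independent lists. It was also set beside 200 simulations with no effect that had normal noise and shared the DMSO libraries. The size of that noise was taken from the observed differences between inhibitor and DMSO, so a real effect would enter it as noise. Alternatives to the pseudocount, the minimum, the centring, the symbols left out and the rules were computed for the counts, the gene lists and the named genes, and for the overlap of the inhibitors only the minimum was varied. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.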

Results

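The 12 libraries covered 3 treatments (DMSO, PRMT1 inhibitor, PRMT4 inhibitor) and 4 gradient fractions, with 1 library for each pair. Summed FPKM was 201967 in the DMSO input and 329897 to 425444 in the others. The DMSO input listed 2906 of the 10706 genes at 0, against 1138 to 2059 in the other 11 libraries. Spearman correlations across genes were 0.62 to 0.71 between the 3 inputs, 0.64 to 0.77 between the ribosome fractions and 0.62 to 0.74 between an input and a fraction. The PRMT4 inhibitor input stood closer to every ribosome fraction (0.66 to 0.74) than to the DMSO and PRMT1 inhibitor inputs (0.64 and 0.62), which correlated at 0.71, and every input and polysome association value of that inhibitor rests on it. No library had a replicate, so no difference below could be set against the spread between cultures.

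Many of the highest values were listed under genes with an exon of another gene on the opposite strand. HERC3 and TKT, at 2531 and 1073 FPKM, had none. SH3D19 (ENSG00000109686), which shares 262 exonic bases with RPS3A on the other strand, averaged 24891 FPKM, while RPS3A, a protein of the small ribosomal subunit, averaged 68.0. MFSD11, opposite the splicing factor SRSF2, averaged 8081, and SRSF2 66.2. ACTB, GAPDH and EEF1A1, mRNAs of actin, a glycolytic enzyme and a translation elongation factor, averaged 47.0, 50.4 and 88.4. MT-ND6, the only mitochondrially encoded mRNA read from the other strand of that genome, averaged 1329, against a median of 95.6 for the other 12. Of the 100 genes with the highest mean, 84% had an exon of another gene on the opposite strand, against 39.3% of all annotated genes in the table. Values below are those listed under a gene's name, and a partner on the opposite strand is given for many of the genes discussed singly. Those values may hold fragments from the other strand. Statements on genes and lists below thus refer to listed values, which need not be those of a gene's own mRNA.

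**Figure D1:**
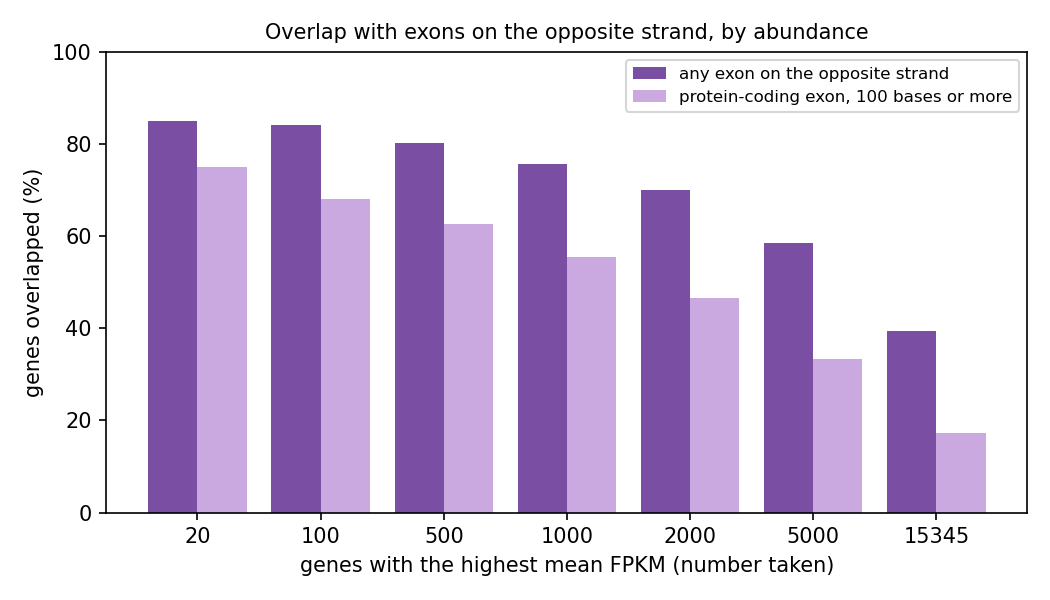
Share of genes (%, y axis) that have an exon of another gene on the opposite strand, among the genes with the highest mean FPKM over the 12 libraries (number of genes taken, x axis). Dark bars count any opposite-strand exon and light bars an overlap of at least 100 bases with a protein-coding exon. The dark bars stand at 84% for the top 100 genes and 39.3% for all 15345.

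The first comparison asked where mRNAs sat in the DMSO gradient. Values listed under histone, spliceosomal and oxidative phosphorylation genes lay toward 3 or more ribosomes. Those under ribosomal protein genes and other mRNAs with a 5' terminal oligopyrimidine tract lay toward 1 ribosome. The median log2 ratio of 3 or more ribosomes to 1 ribosome was -0.65 over 79 cytosolic ribosomal protein genes (percentile 0.155, 42 members at least 1.5-fold lower and 9 higher) and -0.97 over 19 other such mRNAs (percentile 1.09). RPL10, a protein of the large subunit that lies opposite DNASE1L1, was listed at 593 FPKM with 1 ribosome and 232 with 3 or more. RACK1, a scaffold on the small subunit that lies opposite CTC-338M12.4, was listed at 921 and 326. EEF1D, a subunit of elongation factor 1 opposite TIGD5, went the other way, at 306 and 605. The ribosomal protein median was also below 0 with the PRMT1 inhibitor (-0.56) and the PRMT4 inhibitor (-0.39), as was that of the other terminal oligopyrimidine mRNAs (-1.25 and -0.81).

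Replication-dependent histone genes had the highest median gradient position in DMSO, at 1.42 (percentile 99.99), with 11 of 13 members at least 1.5-fold higher with 3 or more ribosomes and 1 lower. H2BC12 was listed at 286 FPKM with 1 ribosome and 1137 with 3 or more, and H2BC5 at 21.8 and 156. H4C3 was lower, at 92.7 and 58.8. The spliceosomal list had a median of 1.21 (29 members, percentile 100), with SNRPD3 at 9.39 and 39.4 and SNRPD2 at 6.85 and 33.8; both have partners on the other strand (GUCD1 and QPCTL). Nuclear-encoded oxidative phosphorylation subunits had a median of 0.75 (62 members, percentile 100), ribosome biogenesis factors 0.71 (percentile 99.4), actin and tubulin cytoskeleton genes 0.64 (percentile 99.2), mitochondrial ribosomal proteins 0.63 (percentile 99.7) and translation initiation factors 0.45 (percentile 97.6).

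**Figure D2:**
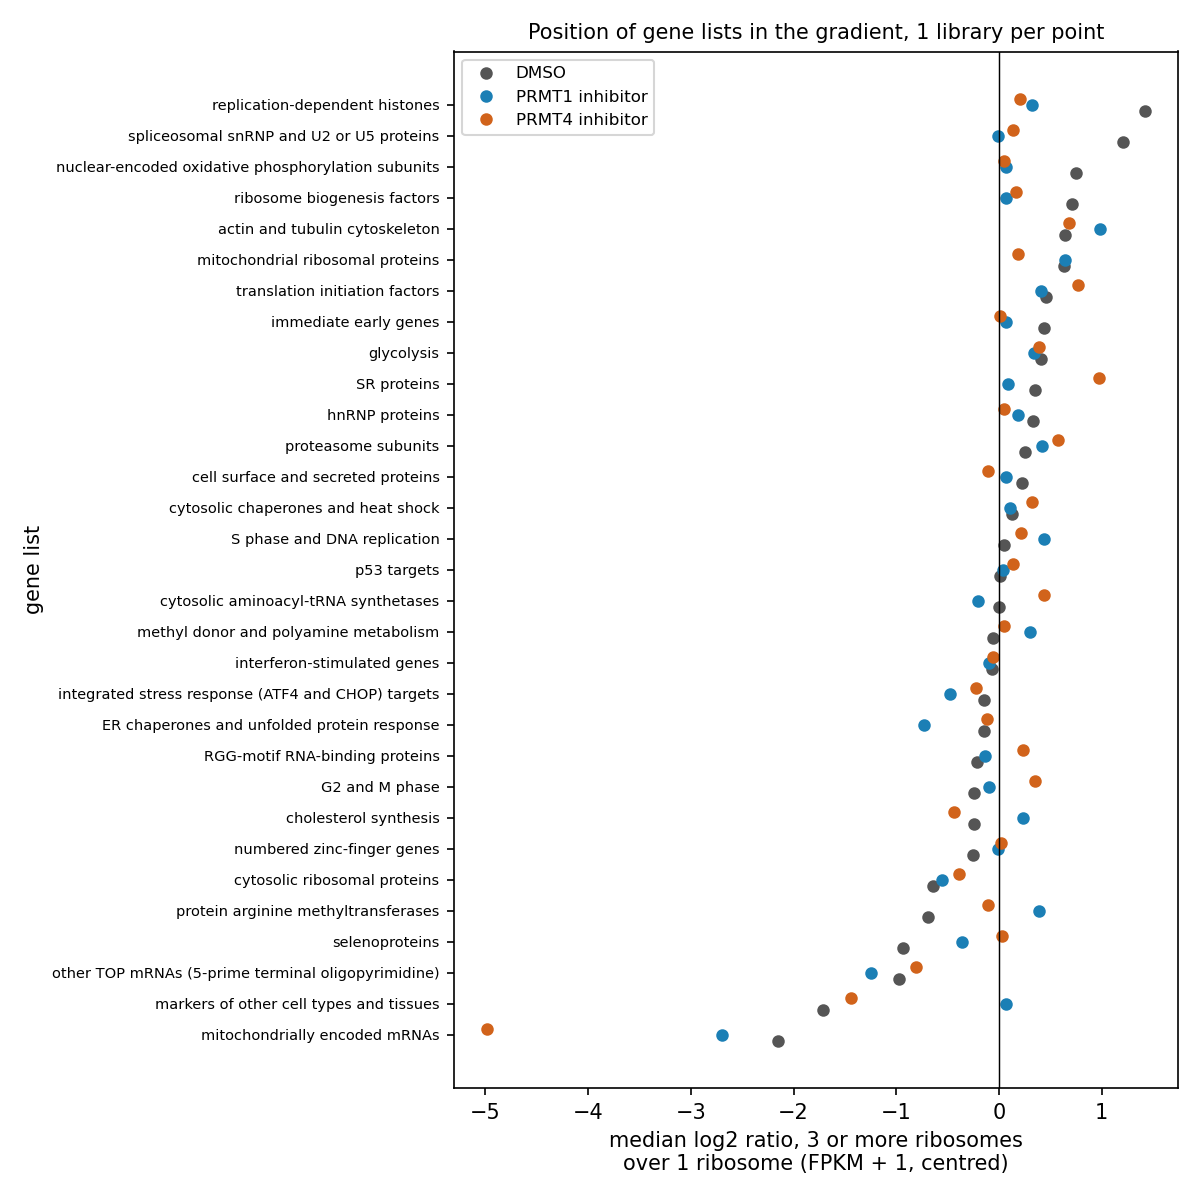
Median log2 ratio of 3 or more ribosomes to 1 ribosome (x axis, FPKM + 1, centred) for 31 gene lists (y axis), 1 point per list and treatment. Replication-dependent histones stand at 1.42 and spliceosomal proteins at 1.21 in DMSO, and mitochondrially encoded mRNAs at -2.15 in DMSO, -2.70 with the PRMT1 inhibitor and -4.98 with the PRMT4 inhibitor.

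The 13 mitochondrially encoded mRNAs, which are translated inside mitochondria and not by cytosolic ribosomes, were depleted from the DMSO fraction of 3 or more ribosomes. Their median was -3.49 against input (percentile 0, 12 of 13 lower after centring) and -2.15 against 1 ribosome (percentile 0). The 12 include MT-ATP8, listed at 0 in the input and with 3 or more ribosomes, whose value of -0.68 comes from centring alone. MT-CYB, a subunit of respiratory complex III, was listed at 947, 267, 208 and 86.7 FPKM in the input and the fractions of 1, 2 and 3 or more ribosomes. Against input, the nuclear-encoded mitochondrial ribosomal proteins (1.04, percentile 99.97), translation initiation factors (1.01, percentile 99.7), proteasome subunits (0.84, percentile 99.6), oxidative phosphorylation subunits (0.82, percentile 99.9) and cytosolic ribosomal proteins (0.61, percentile 99.9) lay above matched lists.

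Under the profile rule, 1144 genes were enriched and 1077 depleted with 3 or more ribosomes in DMSO (20.7% of genes), with 1134 and 1331 under the PRMT1 inhibitor and 1236 and 1144 under the PRMT4 inhibitor. The 5 highest by the ratio to input were COX7C, HSPE1, SIVA1, ERICH6B and MRPS26, which were all listed at 0 in the DMSO input and at 142, 74.0, 65.3, 65.2 and 65.0 FPKM with 3 or more ribosomes. The 5 lowest were MT-ND6, ANO7, MT-ND2, FAM174B and RRP12. MT-ND6, a subunit of complex I, was listed at 5993 FPKM in the DMSO input and 14.9 with 3 or more ribosomes, and MT-ND2 at 116 and 2.09. Without centring, the split was 1620 enriched and 702 depleted, and with higher minima it turned toward depleted genes, at 507 and 687 for a mean FPKM of at least 5 and 56 and 124 for at least 50.

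The second comparison asked which genes differed in abundance with the PRMT1 inhibitor. Mitochondrially encoded mRNAs were lower in its input, with a median log2 difference of -3.75 (13.5-fold, interval -4.43 to -1.96, percentile 0) and 12 of 13 members at least 1.5-fold lower after centring. Among the 12 is MT-ATP8, which was listed at 0 in both inputs and takes its value of -0.68 from centring alone. MT-ND6 was listed at 5993 FPKM in the DMSO input and 79.1 in the PRMT1 inhibitor input, MT-CYB at 947 and 69.2, and MT-ND1 at 178 and 8.50. In the ribosome fractions its medians were near 0 (-0.07, -0.13 and -0.22 with 1, 2 and 3 or more ribosomes), over members that went both ways: with 3 or more ribosomes MT-ND6 was listed at 14.9 FPKM in DMSO and 0 with the inhibitor, and MT-ATP6 at 0 and 17.9. Cytosolic ribosomal proteins were higher in the input (median 0.53, percentile 98.5, 36 of 79 members at least 1.5-fold higher and 19 lower; 1.21 without centring and 0.25 with upper-quartile scaling), as were numbered zinc-finger genes (0.23, percentile 98.6), whose median turned to -0.21 (percentile 49.8) with no minimum.

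The abundance rule was met by 73 genes that were higher and 53 that were lower with the PRMT1 inhibitor, and counting noise alone gave 32. The 8 highest were ZNF414, TRAPPC8, RFX1, BAG1, EIF2D, NINJ2, TNFAIP2 and ZFPL1. TNFAIP2 was the only one of these above 0 in all 12 libraries, at 0.92, 4.80, 2.97 and 0.46 FPKM in the DMSO input and the fractions of 1, 2 and 3 or more ribosomes, and at 21.2, 38.9, 6.15 and 11.2 with the inhibitor. EIF2D, a translation initiation factor, was listed at 0 in the DMSO input and at 13.7 in that of the inhibitor, and BAG1, a partner of HSP70 chaperones, at 0 and 18.0. Among the 8 lowest were MT-ND6, MT-ND1, FBXO21, NIPSNAP2, MXI1, CLNS1A and KCNG1. CLNS1A, a partner of PRMT5 in spliceosomal snRNP assembly, was listed at 4.92, 37.1, 17.0 and 7.49 FPKM in the 4 DMSO libraries and at 0.80, 1.41, 7.09 and 2.01 with the inhibitor. Of the 16 highest and lowest genes, 11 had at least 1 library at 0 and 8 had an exon on the opposite strand. Without centring, the split was 124 higher and 29 lower, and with a mean FPKM of at least 50 it was 0 and 5.

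The third comparison asked which mRNAs differed in gradient position and polysome association with the PRMT1 inhibitor. Nuclear-encoded oxidative phosphorylation subunits lay less toward heavy polysomes than in DMSO, with a median difference in gradient position of -0.68 (interval -1.06 to -0.04, percentile 0.1, 32 of 62 members at least 1.5-fold lower and 15 higher) and in polysome association of -0.60 (percentile 1.16). Histone genes (-0.97, percentile 0.25) and spliceosomal proteins (-0.80, percentile 2.28), which stood highest in DMSO, were also lower in gradient position. The DMSO ratio that placed these lists high is the one subtracted here, so noise in the DMSO libraries would also give a fall. The same lists were lower with the PRMT4 inhibitor, and between the inhibitors their medians lay within the range of matched lists. H2BC12 was listed at 804 FPKM with 1 ribosome and 959 with 3 or more under the inhibitor, against 286 and 1137 in DMSO. Proteasome subunits were lower in polysome association (-0.83, percentile 1.22, 16 of 30 members at least 1.5-fold lower and 8 higher), with PSMD1, opposite HTR2B, at 11.6 FPKM in the input and 65.9 with 3 or more ribosomes in DMSO and at 36.1 and 12.4 with the inhibitor. Over the 21 subunits without an opposite-strand exon, the median was 0.02 (percentile 52.2).

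Immediate early genes, induced by growth signals, were higher in polysome association with the PRMT1 inhibitor (1.03, percentile 98.7, 12 of 21 members at least 1.5-fold higher and 3 lower). Centring added 0.73 (log2) to every member, enough by itself to count as 1.5-fold higher. Their median was -0.47 in the input, the denominator of that ratio, and 0.02 in gradient position, and that of polysome association was 0.30 without centring. MYC was listed at 69.5 FPKM in the input and 53.9 with 3 or more ribosomes in DMSO and at 63.1 and 101 with the inhibitor, and JUND at 31.5 and 42.6 against 52.1 and 86.7. The mitochondrially encoded mRNAs were higher by this ratio (2.96, percentile 100), and their difference lay in the input. Markers of other cell types, of which 6 were measured, had a gradient position 1.64 above that in DMSO (percentile 99.1); 4 were at least 1.5-fold higher, and HBA1 and HBA2, globin genes with near-identical sequences, went in opposite directions.

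The translation rule was met by 1672 genes that were higher and 1716 that were lower with the PRMT1 inhibitor, and counting noise alone gave 2036, or 60.1% of that number. The 8 highest were KLHL28, OSBPL10, HBA2, MT-ATP6, CDC42SE2, MT-ATP8, IQSEC1 and H2AC16, and the 8 lowest were C8G, SAFB, HBA1, DCK, CATSPERZ, RPL35A, TPSG1 and DENND5B. All 16 were listed at 0 in at least 1 library, with a median of about 10.7 fragments per library. KLHL28, opposite TOGARAM1, was listed at 11.8 FPKM in the DMSO input and 0 with 3 or more ribosomes, and at 0 and 52.2 with the inhibitor. DCK, deoxycytidine kinase, was listed at 0 and 16.4 in DMSO and at 49.2 and 0.75 with the inhibitor, and SAFB, an RNA-binding protein, at 0 and 28.6 against 30.9 and 0. Without centring the split was 1139 higher and 2389 lower. Among 1191 genes with a mean FPKM of at least 50, 64 were higher and 83 lower, and counting noise gave 28.

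The fourth comparison asked which genes differed in abundance with the PRMT4 inhibitor. Histone genes were lower: the median input difference of 13 replication-dependent histone genes was -2.01 (4.03-fold, interval -3.13 to -1.72, percentile 0), with 11 at least 1.5-fold lower and 1 higher; without centring it was -1.44. Their medians were also below those of DMSO with 2 ribosomes (-0.56, percentile 0.07) and with 3 or more (-0.75, percentile 0), and not with 1 ribosome (0.18). Of the 13, 5 were lower in all 4 libraries and 1 met the abundance rule. H1-4, a linker histone, was listed at 2286 FPKM in the DMSO input and 55.2 in that of the inhibitor, H2BC12 at 492 and 67.7, and H2AC20 at 244 and 97.8. H1-5 went the other way, from a value listed at 0 to 7.38.

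**Figure D3:**
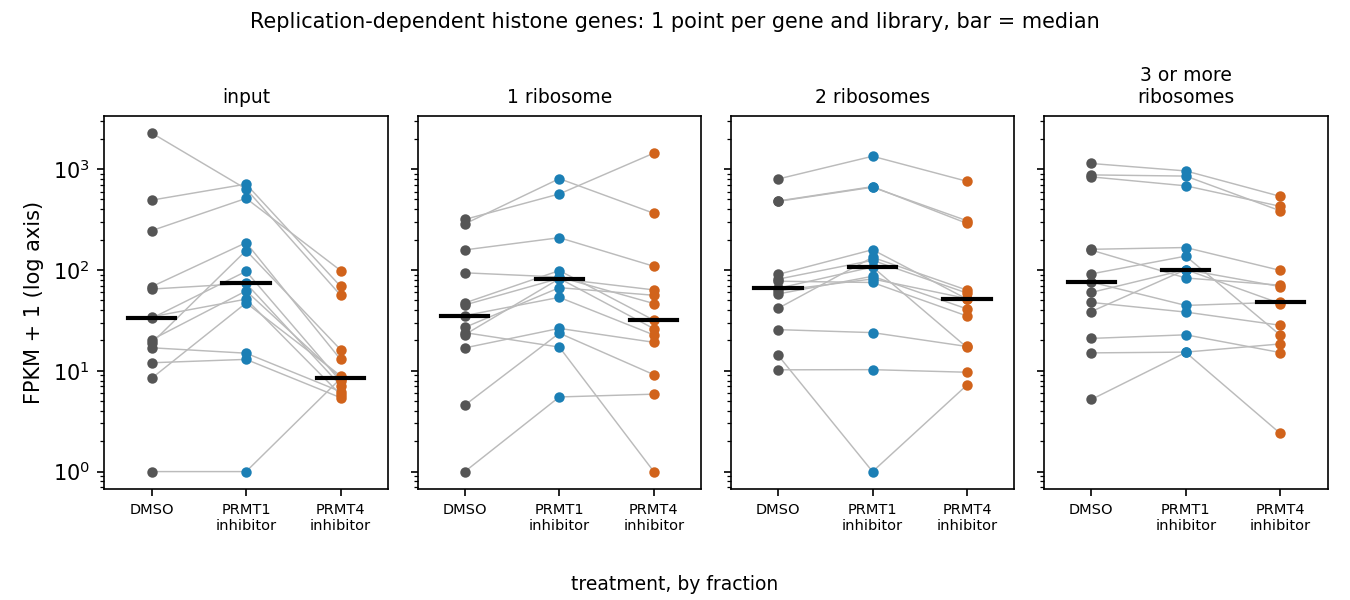
FPKM + 1 (y axis, log scale) of 13 replication-dependent histone genes in each treatment (x axis), 1 panel per fraction. Points are genes in 1 library each, grey lines join the same gene, and black bars are medians. The input medians stand at 32.2 FPKM in DMSO, 72.5 with the PRMT1 inhibitor and 7.48 with the PRMT4 inhibitor.

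Glycolysis genes were also lower in the PRMT4 inhibitor input (-1.12, percentile 0, 13 of 21 members at least 1.5-fold lower and 4 higher), with LDHA, lactate dehydrogenase, at 62.7 FPKM in DMSO and 5.64 with the inhibitor and ALDOA, aldolase opposite AC093512.1, at 201 and 124. Actin and tubulin cytoskeleton genes had a median of -0.98 (percentile 0.05, interval -1.99 to 0.55), with PFN1, the actin-binding protein profilin opposite ENO3, at 165 and 55.4 and TUBB6, a tubulin opposite AFG3L2, at 112 and 331. Immediate early genes had a median of -0.73 (percentile 0.32). Without centring, the glycolysis, cytoskeleton and immediate early medians were smaller, at -0.55, -0.42 and -0.16. Numbered zinc-finger genes were higher (0.38, percentile 99.6, 86 of 199 members at least 1.5-fold higher and 34 lower). Mitochondrial ribosomal proteins, oxidative phosphorylation subunits, spliceosomal proteins, S phase genes and hnRNP proteins each had a median of -0.57, which before centring was 0 within 0.01. With upper-quartile scaling the median was 0 for mitochondrial ribosomal proteins and oxidative phosphorylation subunits, -0.74 for S phase genes and -0.58 for hnRNP proteins. These medians thus depend on the scaling. A value of -0.57 is also what centring gave a gene listed at 0 in both inputs, such as COX7C. Before centring, the S phase list had 17 members lower, 15 higher and 3 at 0 in both inputs. The spliceosomal median was 0.285 (percentile 64.0) over the 19 members without an opposite-strand exon. The median of the cytosolic ribosomal proteins was -0.17 (percentile 2.32), turned to 0.40 without centring and was -0.52 with upper-quartile scaling.

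The abundance rule was met by 127 genes that were higher and 70 that were lower with the PRMT4 inhibitor, and counting noise alone gave 31. The 8 highest were FOLR3, GNPTAB, GDPD3, TUBA8, CCNG1, FLVCR2, HMOX1 and OGN. HMOX1, heme oxygenase 1, was listed at 0, 1.13, 6.85 and 4.84 FPKM in the DMSO input and the fractions of 1, 2 and 3 or more ribosomes and at 12.7, 38.7, 30.1 and 42.7 with the inhibitor. OGN, a matrix proteoglycan, was listed at 4.15, 30.9, 41.7 and 18.6 against 66.7, 51.7, 67.1 and 56.1. CCNG1, a p53 target, was listed at 0 in the DMSO input and 19.1 in that of the inhibitor. The 8 lowest were H3C7, CBX7, H2AC4, RNASEH2A, ITPK1, NUDT14, DCXR and STMN3, with 2 histone genes among them. DCXR, a sugar reductase, was listed at 43.4, 58.5, 57.6 and 95.9 FPKM in DMSO and at 7.01, 27.8, 19.8 and 40.5 with the inhibitor, and STMN3, a stathmin, at 13.8, 11.9, 10.3 and 13.7 against 1.87, 2.64, 5.65 and 7.06. H3C7 was listed at 14.1 in the DMSO input and 0 in that of the inhibitor, and CBX7, a Polycomb protein opposite AL031846.2, at 11.4 and 0. Of these 16 genes, 11 had at least 1 library at 0 and 5 had an exon on the opposite strand. Without centring, the split was 175 higher and 46 lower.

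Among genes with a mean FPKM of at least 50, a minimum chosen after the values were seen, 5 met the abundance rule as higher (EXOSC8, ESYT1, MBD6, GNPTG and LHX4, all with an opposite-strand partner) and 9 as lower, and counting noise gave 0. Of the 9, 6 were histone genes (H3C13, H3C10, H4C14, H2AC25, H2BC17 and H4C4) and the others were HOXA7, GAS8 and RPL35. H3C13 was listed at 253, 521, 1223 and 1557 FPKM in the 4 DMSO libraries and at 68.7, 284, 602 and 648 in those of the PRMT4 inhibitor. H2BC17 was listed at 95.2, 253, 623 and 379 against 50.8, 74.7, 364 and 112.

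The fifth comparison asked the same of the PRMT4 inhibitor. Mitochondrially encoded mRNAs differed most: their gradient position was 3.56 below that in DMSO (median -3.56, interval -4.29 to -1.65, percentile 0, 12 of 13 members at least 1.5-fold lower). The difference lay in the 1-ribosome library, where MT-CYB was listed at 3703 FPKM against 267 in DMSO, MT-ND5 at 2110 against 282 and MT-ND6 at 8280 against 70.5. Spliceosomal proteins (-1.09, percentile 0.32), histones (-0.73, percentile 0.66) and oxidative phosphorylation subunits (-0.40, percentile 1.80) were lower in gradient position. Both inhibitors were set against the same DMSO libraries, and between the inhibitors these medians were 0.31, -0.22 and -0.16, within the range of matched lists. SNRPD2 was listed at 29.4 FPKM with 1 ribosome and 13.4 with 3 or more under the inhibitor, against 6.85 and 33.8 in DMSO.

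**Figure D4:**
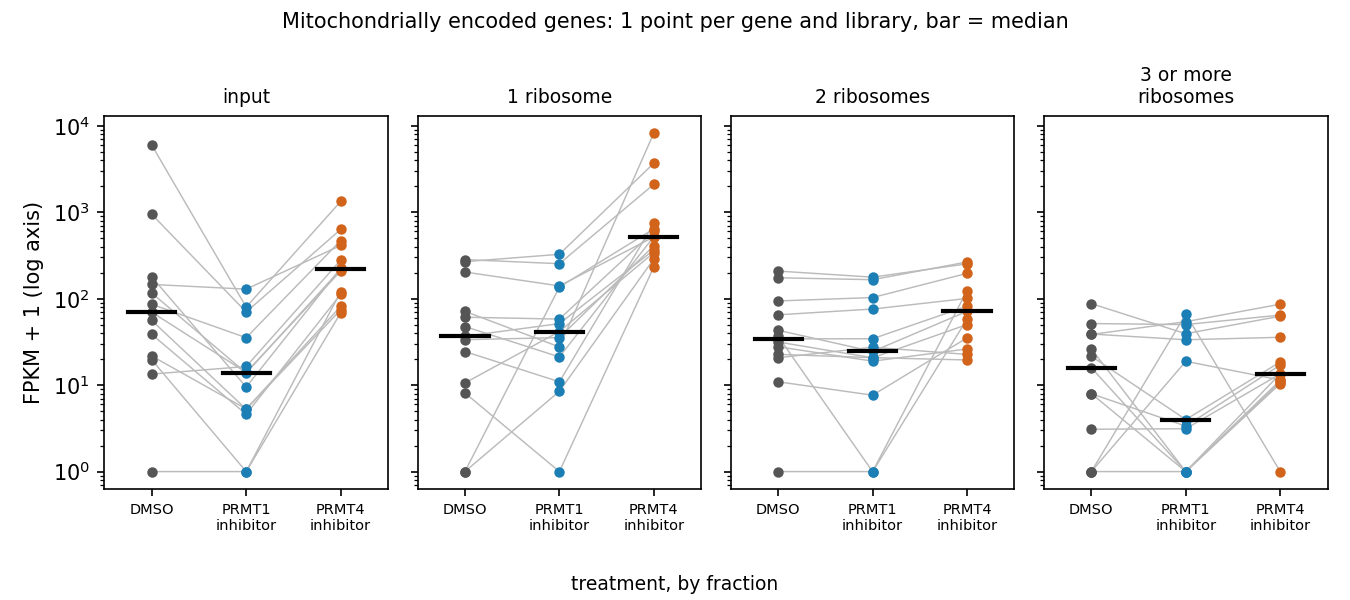
FPKM + 1 (y axis, log scale) of the 13 mitochondrially encoded genes in each treatment (x axis), 1 panel per fraction. Points are genes in 1 library each, grey lines join the same gene, and black bars are medians. With 1 ribosome the medians stand at 35.8 FPKM in DMSO, 40.7 with the PRMT1 inhibitor and 522 with the PRMT4 inhibitor.

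Histone and glycolysis genes were higher in polysome association with the PRMT4 inhibitor (medians 1.62, percentile 100, and 1.04, percentile 99.8; 0.98 and 0.39 without centring). Both lists were lower in the input, which is the denominator of that ratio. The translation rule was met by 1512 genes that were higher and 1489 that were lower, and counting noise alone gave 2005, or 66.8% of that number. Among the 8 highest were DPM3, ANO7, BLTP2, UBXN8, FADS3, CMC2 and H2AC21, and the 8 lowest were CFAP20, COPS3, CTIF, DPP9, PRXL2C, OST4, IMPA2 and PNO1; 15 of the 16 were listed at 0 in at least 1 library. H2AC21, a histone gene opposite BOLA1, was listed at 52.8 FPKM in the DMSO input and 123 with 3 or more ribosomes, and at 0 and 122 with the inhibitor. CMC2, opposite CENPN and above 0 in all libraries, was listed at 7.36 and 0.92 in DMSO and at 0.39 and 17.8 with the inhibitor. CTIF, a translation initiation factor that acts with the nuclear cap-binding complex, was listed at 0 and 16.1 against 12.6 and 0. Without centring the split was 1080 higher and 1965 lower. Among genes with a mean FPKM of at least 50, 50 were higher and 47 lower, and counting noise gave 26.

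The sixth comparison set the inhibitors against each other. In the input, mitochondrially encoded mRNAs were higher with the PRMT4 inhibitor than with the PRMT1 inhibitor (median 4.02, percentile 100, 13 of 13 members), and histones (-3.11, percentile 0, 12 of 13), glycolysis genes (-1.29, percentile 0.185), hnRNP proteins (percentile 1.47, 12 of 22 members at least 1.5-fold lower and 6 higher) and cytosolic ribosomal proteins (-0.63, 41 of 79 lower and 14 higher) were lower. H2BC5 was listed at 72.5 FPKM in the PRMT1 inhibitor input and 6.14 in that of the PRMT4 inhibitor, against 63.7 in DMSO. Polysome association was higher with the PRMT4 inhibitor for histones (2.42, percentile 100) and p53 targets (1.30, percentile 99.7, 15 of 22 members at least 1.5-fold higher and 5 lower), while the gradient position of p53 targets had a median of -0.58 (percentile 6.49). The abundance rule was met by 146 genes that were higher and 154 that were lower with the PRMT4 inhibitor (31 from counting noise), and the translation rule by 1730 and 1703 (1977 from counting noise).

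TNFAIP2, ZNF552, SNX15, CBX8 and UBXN1 were among 8 genes that met the abundance rule as higher with both inhibitors, and NIPSNAP2 was among 4 that met it as lower. ZNF552, a zinc-finger gene opposite ZNF586, was listed at 2.37 FPKM in the DMSO input and 27.3 in that of the PRMT4 inhibitor, and at 6.79, 16.6 and 26.9 with 3 or more ribosomes in DMSO, the PRMT1 inhibitor and the PRMT4 inhibitor. Independent lists would share 0.9 and 0.3 genes, and simulated libraries with no effect that share the DMSO libraries gave 4.2 and 4.0. For the translation rule, 555 genes were higher and 575 lower with both, against 236.1 and 238.7 for independent lists and 575.4 and 575.3 in the simulation, and 149 genes met the rule in opposite directions. The covariance of the input differences was 0.75 (simulated 0.83) and that of the polysome association differences was 1.67 (simulated 1.43). Both differences of each pair use the same DMSO libraries. The noise of the simulation came from the observed differences, so a match with it does not show an absence of shared effects.

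The genes of the inhibited enzymes were measured at very different depths. PRMT1 (ENSG00000126457, with AC011495.3 on the other strand) was listed at 16.2, 28.3, 22.7 and 31.4 FPKM in the 4 DMSO libraries, at 24.8, 6.73, 22.5 and 17.4 with the PRMT1 inhibitor and at 1.90, 15.2, 16.1 and 13.9 with the PRMT4 inhibitor, with about 7.04 fragments per library. CARM1, which encodes PRMT4 (ENSG00000142453), was listed at 62.0 to 142 FPKM in DMSO, 89.7 to 154 with the PRMT1 inhibitor and 95.9 to 133 with the PRMT4 inhibitor, and lies opposite YIPF2. PRMT6 was listed at 28.8 to 66.4, 22.4 to 54.5 and 19.1 to 51.0. PRMT5 was listed at 0 in 2 of the 12 libraries and PRMT2, PRMT3, PRMT7 and PRMT9, with mean FPKM of 4.52, 1.41, 2.87 and 2.37, in 3, 5, 6 and 3. These 5 genes had under 5 estimated fragments per library on average, too few to read a difference. PRMT8 was not analysed here.

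The lists of RNA-binding proteins lay within the range of matched lists in polysome association with both inhibitors. The median polysome association difference of RNA-binding proteins with RGG motifs, such as G3BP1, was -0.22 with the PRMT1 inhibitor (percentile 33.6) and 0.04 with the PRMT4 inhibitor (percentile 57.3). That of SR proteins was -0.13 (percentile 42.5) and 0.05 (percentile 53.4), and that of hnRNP proteins 0.11 (percentile 69.9) and 0.01 (percentile 59.3). Of 31 lists, 3, 4 and 4 lay outside the central 95% of matched lists for input, polysome association and gradient position with the PRMT1 inhibitor, and 11, 2 and 4 with the PRMT4 inhibitor. Before centring, 7 of the 31 lists had a median PRMT4 inhibitor input difference of 0 within 0.01, spliceosomal and hnRNP proteins among them.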

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

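The 10 counts were recomputed under 79 alternatives, the medians of 31 lists (341 results) under 2464 and the 74 results of named genes under 498. Alternatives without the inputs, without opposite-strand genes, with the ratio to 2 ribosomes and with a mean FPKM of at least 50 were chosen after seeing the data. No named gene changed direction, which says little because these genes were picked for the largest differences. With a pseudocount of 0.1 the value of 57 of the 74 results moved. The cause of a move was not tested unless a smaller set of genes is named. No paired analysis was possible because each group had 1 library, so that the groups shared fewer than 2 replicate numbers, and no result came from a test.

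Dropping parts of a rule raised the counts. By the input alone, 4214 genes differed with the PRMT1 inhibitor and 5105 with the PRMT4 inhibitor, and by the 3 fractions without the inputs 489 and 548. By 3 or more ribosomes over input alone, 5714 and 6014 differed, and over 1 ribosome without the inputs 5600 and 5622; the DMSO profile without the input held 5254 genes. With a pseudocount of 0.1, 194 genes met the abundance rule with the PRMT1 inhibitor.

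Higher minima tested fewer genes. At a mean FPKM of at least 5, abundance counts were 63 and 118, translation counts 1607 and 1340, the DMSO profile 1194, the direct comparison 174 and 1637, and the overlap of the translation lists 477. At a mean of at least 50 they were 5 and 14, 147 and 97, 180, and 29 and 160, and 13 list results of the inhibitors against DMSO lay outside the central 95%, against 28 at the lower minimum, with 9 lists in place of 31. Genes without an opposite-strand exon, also fewer, gave 69 and 118, 1996 and 1816, 1364, and 180 and 2031.

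Some list medians changed sign. For ribosomal proteins in the PRMT4 inhibitor input, the median was 0.24 with no minimum (percentile 2.48) and 0.40 without centring (percentile 2.32). For hnRNP proteins in that input it was 0.0007 without centring (percentile 1.71). Both lists thus stayed low among matched lists although the sign changed. For numbered zinc-finger genes in the PRMT1 inhibitor input, it was -0.21 with no minimum, where 372 genes entered. Without opposite-strand genes, the spliceosomal median in the PRMT4 inhibitor input was 0.285 and the proteasome median of polysome association with the PRMT1 inhibitor was 0.0197.

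With no minimum, the higher and lower parts were 103 and 37 for PRMT1 inhibitor abundance (73 and 53 before), 163 and 53 for PRMT4 inhibitor abundance (127 and 70) and 1706 and 879 for the DMSO profile (1144 and 1077).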

Other observations

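EEF2, the elongation factor that moves the ribosome along the mRNA, met the translation rule as higher with both inhibitors and was chosen after its values were seen. It was listed at 79.9, 329, 102 and 62.0 FPKM in the DMSO input and the fractions of 1, 2 and 3 or more ribosomes, at 132.5, 232, 103 and 229 with the PRMT1 inhibitor and at 56.9, 292, 192 and 188 with the PRMT4 inhibitor. It has no exon on the opposite strand and about 260 fragments per library. EEF2 was among 555 genes that met the rule as higher with both inhibitors, against a mean of 575.4 in simulations with no effect. Both calls use the same DMSO libraries.

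The 50 measured genes with a histone symbol, a set also chosen after the values were seen, had a median of -1.92 in the PRMT4 inhibitor input (38 at least 1.5-fold lower and 4 higher) and of -0.60, -0.56 and -0.78 with 1, 2 and 3 or more ribosomes. Of these 50, 24 were lower in all 4 libraries, against 6.32% of all genes, and 9 met the abundance rule. With the PRMT1 inhibitor the input median was 0.60.

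Of the tests on strand, the one on SH3D19 was chosen after the result was seen. The very high values under genes that lie opposite another gene may come from fragments counted on the wrong strand. Over 1088 overlapped genes, gradient position in DMSO followed the coding length of the opposite gene (rho 0.139, interval 0.080 to 0.198). It did not follow that of the listed gene (-0.0429, interval -0.10 to 0.016), and the difference between these rhos was 0.182 (interval 0.098 to 0.262). Reading this against the listed genes being that abundant assumes that gradient position rises with the coding length of the mRNA counted. Own coding length showed no such rise in genes without an overlap, so the comparison does not decide this. Counting without regard to strand would give SH3D19 a value near that of ribosomal proteins, and it stood 382 times above them. Wrong-strand fragments as a small share of a gene's own mRNA predicted a positive rho with own coding length. Over 808 genes without an overlap, rho was -0.148 (interval -0.221 to -0.077). That prediction rests on the same assumption, so this source is not decided either. For the overlapped genes, these values thus did not decide between wrong-strand counting and listed genes that are that abundant. The strand setting of the counting was not given, so wrong-strand counting was not shown directly.

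All tests on the mitochondrial genes were chosen after the result was seen. Their high values in the PRMT4 inhibitor 1-ribosome library could come from more mitochondrial RNA in those cells, and their input median was also higher than in DMSO (0.97, log2). As the whole cause this was argued against, since the difference with 1 ribosome exceeded that of the heavier fractions by 2.83. Scaling or depth of the library was argued against by a gap of 4.25 to the ribosomal protein genes. Mitochondrial RNA collected in that part of the gradient (3.26 for 1 ribosome over input) cannot be told apart from an effect of the inhibitor, because each treatment had 1 gradient.

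All tests on the histone genes were chosen after the result was seen. Lower histone RNA with the PRMT4 inhibitor could reflect fewer cells in S phase. The S phase list had a median of -0.57 with centring, 0 before it and -0.74 with upper-quartile scaling. As its fall depends on the scaling, the cell cycle cannot be told apart from other causes. Neighbours on the opposite strand were not tested: all 13 genes lack an annotated exon there, so the value for genes without any (-2.01) is that of the list itself. A DMSO input that stands apart was argued against, as the histone median against the PRMT1 inhibitor was -3.11. A PRMT4 inhibitor input that stands apart stays open, because both comparisons use that 1 library, which correlated less with the other inputs (0.64 and 0.62) than with the ribosome fractions, and the list was lower than in DMSO by less with 2 (-0.56) and 3 or more ribosomes (-0.75).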
